A study of Homo sapiens with 2 samples.

How the data were processed

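Total RNA of PC3 cells transfected with a control siRNA (1 sample) or with LASP1 siRNA (1 sample) was amplified, labelled with Cy3 and hybridised to Agilent single-colour human arrays, per the labels' protocols. Groups were taken from the siRNA label of each sample. The arrays lay side by side on 1 slide and came from the same scan, so slide and scan do not separate the groups.

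The authors deposited the scanner output of each array and a value table. Per the file headers, spots were quantified with Feature Extraction 11.0.1.1, and the values are intensities: a processed signal after background subtraction within the array, the background-subtracted signal before detrending, and median spot and local background brightness. Per the file headers, a multiplicative detrending surface was fitted and applied on the control siRNA array only (fit residual 0.135, against 0 where none was applied), which is a processing step that differs between the groups. The authors' deposited value table holds log2 values on a common scale. Its columns correlate at 0.995 (control siRNA) and 0.996 (LASP1 siRNA) with the log2 scanner signal of the same array, across probes, and both have a median of 6.88 with identical quartiles, as after quantile normalization. The submitters' processing notes name RMA. The table is not centred per gene and has 1 value per probe, and the background correction behind it is not given in the sources used here.

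Each array held 44495 spots, of which 43118 were non-control spots for 34127 probes; 33128 probes were printed once and 999 were printed 10 times. Probes were named by matching the accession in the files, without its version, to RefSeq annotation of GRCh38.p14, which was used for names only. Of the probes, 25771 matched 1 gene and none matched several, which gave 19740 genes; 8356 probes had no match and were not used. No coordinates are given because the probe annotation in the files is on another build.

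The main values were log2 processed signals minus each array's 75th percentile over non-control spots. Control spots were left out, as were spots marked as outliers for uniformity or population (253 and 397 spots). Spots of 1 probe were averaged, and the probe with the highest mean log2 signal stood for its gene. A gene was kept if well above background on at least 1 array. Where it was dim on the other, the difference was a bound against the higher of the dim value and the lowest signal well above background on that array. The threshold was 2-fold, a log2 difference of 1. No test was run and no p-value is given, since each group has 1 array. The depth of an array is its signal over background: negative control spots averaged -1.69 intensity units (SD 2.30, 153 spots) on the control siRNA array and -2.46 (SD 1.98) on the LASP1 siRNA array. Technical error came from the probes printed 10 times, as the SD of the log2 difference over copies, and covers neither culture nor hybridisation.

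For 32 gene lists, the median log2 difference of members measured on both arrays was placed as a percentile among 10000 random lists of the same size, matched on mean signal in 20 bins. A list counted as outside below percentile 2.5 or above 97.5 if at least 8 members were measured. The lists, the settings and the rule for named genes were fixed before the data were examined. That rule took LASP1 and NEBL, the 12 genes most strongly higher and 12 most strongly lower above the median brightness (same direction in all their probes, after quantile normalization and in the authors' value table), up to 4 members of each list with the largest difference (up to 2 for other cell types), and the 5 brightest genes seen on 1 array only, in each direction. Of the list members so chosen the report prints 1 to 4 per list and leaves out most dim ones. A few genes that the rule takes are not reported here. A further 4 genes printed 10 times were chosen after their values were seen.

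Alternatives were quantile normalization, a shift by the median of probes above background on both arrays, cyclic loess, normexp background correction with an offset of 50 on median spot signals, the authors' value table, other filters on dim genes, the mean over a gene's probes, and random lists without matching. The design named mean spot signals for normexp. Median signals were used because they are the ones analysed here. The offset of 50 is added to every spot, so it shrinks the differences of dim genes by itself. After the data were examined, 3 more were added: the disturbed tiles left out, the local median subtracted, and the signal before detrending. The array was divided into tiles of 20 rows by 8 columns, and a tile was called disturbed when copies of repeated probes deviated from their probe's median over 2.5 times as far (root mean square) as in the median tile, where this was 0.194. The local median was taken over spots within 10 rows and 5 columns.

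The 2-fold threshold was tested on simulated data for the comparison of LASP1 siRNA with control siRNA, with technical spot noise only, on 17358 genes. That noise came from repeated probes outside the disturbed tiles, not matched on brightness, so the outcome does not cover the disturbed area. Scaling, probe choice and the filter on dim genes were not part of it. All of 200 genes changed 3-fold were recovered, as were all changed 6-fold, and 5 of 200 changed 1.5-fold, with 101 to 113 false calls among the rest. List percentiles were tested on the measured differences. Of 100 random lists of 30 genes, 3 fell outside the range, and 99 of 100 did when shifted by 0.3. The first of these follows from how the percentile is built. Shifts smaller than 0.3, as most list medians below are, were not tried. Computation used Python 3.11, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.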

Results

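PC3 is an established prostate cancer cell line, derived from a bone metastasis, that largely lacks androgen receptor activity. LASP1 encodes an actin-binding scaffold protein with a LIM and an SH3 domain, found at focal adhesions and other sites of actin assembly. Gene expression was measured in PC3 cells transfected with a control siRNA and in PC3 cells transfected with an siRNA against LASP1, on 1 single-colour Agilent array per group. The comparison asks which transcripts differ when LASP1 is depleted. The median signal of the non-control spots was 141.8 intensity units on the control siRNA array and 141.7 on the LASP1 siRNA array. Of the probes, 88.0% were well above background on the control siRNA array and 84.9% on the LASP1 siRNA array, and no spot was saturated. With 1 array per group there is no replicate, no test and no p-value, and every difference below describes these 2 arrays. The number of arrays limits the precision. The only error that could be measured was technical: for the probes printed 10 times on each array, the median SD of the log2 difference between copies was 0.18, from 0.52 in the dimmest 20% of probes to 0.16 in the brightest 20%.

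LASP1 was 5.74-fold lower in the cells given LASP1 siRNA. Its single probe (NM_006148) read 6691 intensity units on the control siRNA array and 1151 on the LASP1 siRNA array, a log2 difference of -2.52. The technical SD for probes of this brightness is 0.16, so the difference is many times that spread, and it follows the sample labels. NEBL, the gene of nebulette and the closest paralog of LASP1, had log2 differences of -0.26 and -0.05 in its 2 probes, of which the first lay in a disturbed part of the array (described next). NEBL turned to 0.17 with normexp background correction, 0.23 after the local median was subtracted and 0.18 with the signal before detrending. The remaining LASP1 signal on the LASP1 siRNA array was well above background.

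Across 18067 named genes, 288 were at least 2-fold higher and 398 at least 2-fold lower in the LASP1 siRNA sample, so that 42.0% of the genes past 2-fold were higher. Of these, 206 higher and 210 lower genes were measured above background on both arrays, and the others entered as bounds. Much of the lower set came from one part of the array. Copies of the same probe disagreed strongly in 53 of 293 tiles, mostly from row 361 on in columns 1 to 40 and along the right edge, and these tiles held 17.9% of the spots. Copies scattered more inside these tiles on both arrays, and most on the LASP1 siRNA array. The root mean square deviation was 1.33 inside and 0.46 outside on the LASP1 siRNA array, against 0.94 and 0.49 on the control siRNA array. Among probes printed once, 9.18% were at least 2-fold lower inside these tiles and 0.301% outside, while 3.06% and 0.899% were at least 2-fold higher. With the disturbed tiles left out, 183 genes were at least 2-fold higher and 82 at least 2-fold lower, so that 69.1% were higher. The share was 53.4% in the authors' value table and 71.5% with normexp, which here also used median spot signals and an offset.

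**Figure D1:**
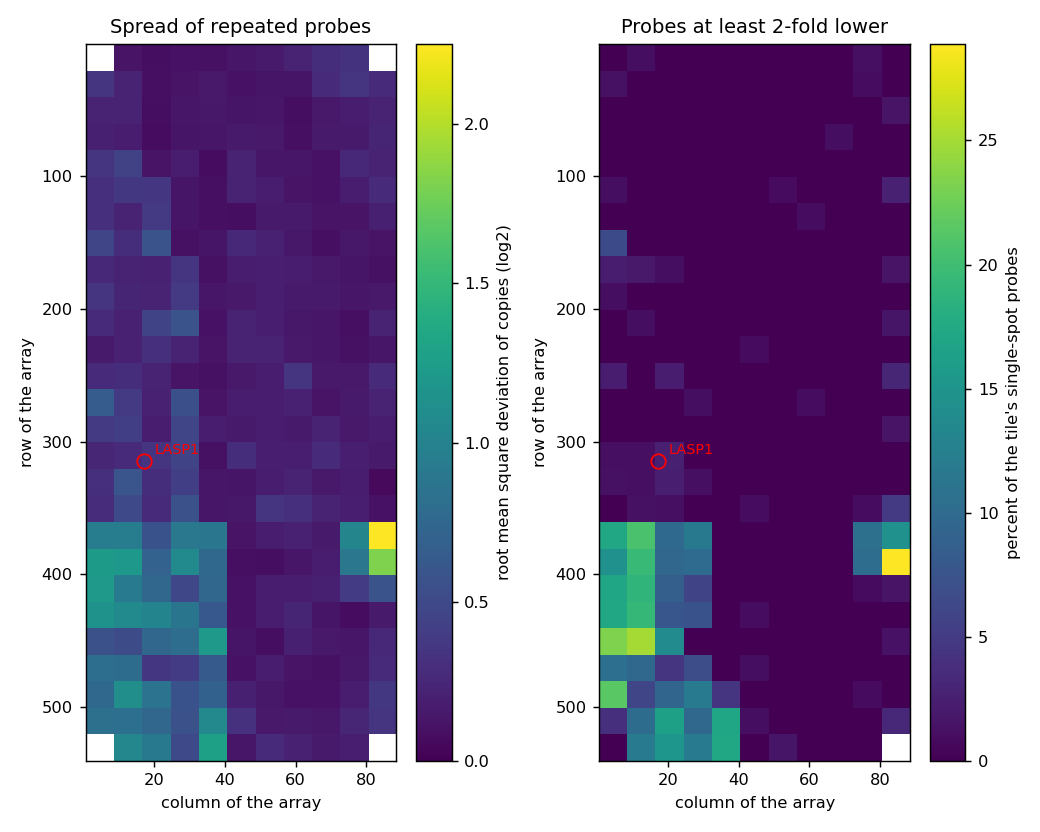
Maps of the array surface in tiles of 20 rows by 8 columns, with rows and columns of the array on the axes. The left map shows how far copies of one probe deviate from that probe's median log2 difference, and the right map the percent of single-copy probes at least 2-fold lower with LASP1 siRNA. Both are raised mostly from row 361 on at the left and at the right edge, although several tiles with a high spread, mainly in columns 33 to 40, held no lower probe. The LASP1 spot (red circle, row 315, column 17) lies outside the disturbed tiles. Its tile had a copy deviation of 0.336 (root mean square), against 0.194 in the median tile, and touches a disturbed tile at a corner. White tiles held too few repeated spots.

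Outside the disturbed tiles, 138 genes measured on both arrays were at least 2-fold higher and 42 at least 2-fold lower. The scatter between copies of one probe, matched on brightness, would alone give 72.3 and 28.7. Most of that expectation lies among dim genes. In the range of the brightest 40% of probes, 48 genes were higher and 10 lower, and none of 4443 copies of repeated probes deviated that far. Disturbed tiles were left out because of this same scatter, so the numbers expected from it lean low. Bright genes are still the better measured, and those named first below lie above the median brightness.

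**Figure D2:**
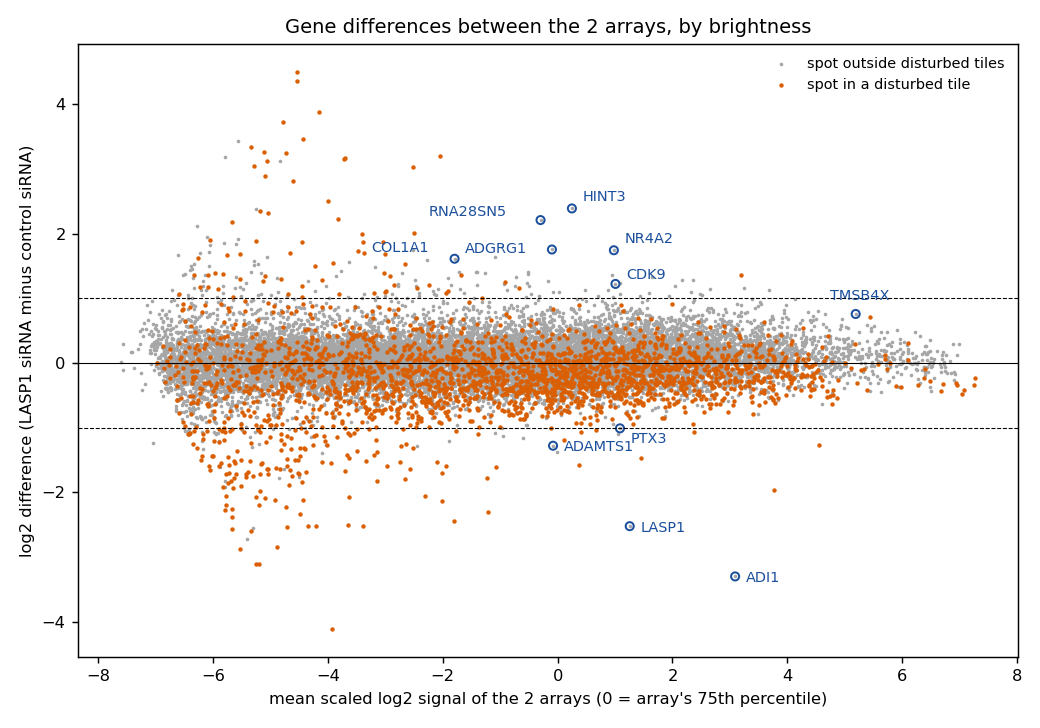
Log2 difference (LASP1 siRNA minus control siRNA) of each gene measured on both arrays against its mean scaled log2 signal, where 0 is each array's 75th percentile and dashed lines mark 2-fold. Orange points are genes whose spots lay in disturbed tiles and grey points all others. LASP1 (-2.52) stands apart among the bright genes, with ADI1 (-3.30) below it and HINT3 (2.39) and RNA28SN5 (2.21) the highest of those circled.

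The bright gene most strongly higher with LASP1 siRNA was HINT3, a member of the histidine triad family of nucleotide hydrolases, at 5.25-fold (607 against 3145 intensity units, log2 difference 2.39). Ribosomal RNA followed: RNA28SN5, the large-subunit rRNA, was 4.63-fold higher, and its 4 probes gave log2 differences from 1.86 to 2.38. ADGRG1, an adhesion G protein-coupled receptor also known as GPR56, was 3.38-fold higher. NR4A2, an orphan nuclear receptor induced early after many stimuli, was 3.35-fold higher by its brighter probe, while its second probe, in a disturbed tile, gave a log2 difference of only 0.39. SYT12, of the synaptotagmin family, was 3.13-fold higher. SNED1, an extracellular matrix glycoprotein, was 2.67-fold higher, and SCARA5, a scavenger receptor that binds ferritin, 2.66-fold. HOXA3, a homeobox transcription factor, was 2.65-fold higher. SCG2, a secretogranin of dense-core granules, was 2.63-fold higher, and TMEM38B, a cation channel of the endoplasmic reticulum, 2.59-fold by its brighter probe and by a log2 difference of 0.78 in the other. PMEPA1, an inhibitor of TGF-beta signalling that TGF-beta itself induces, was 2.56-fold higher by its brighter probe and 1.38-fold by the other. SIGLEC9, at 2.57-fold, was the 1 gene of these 12 in a disturbed tile. The technical SD for these genes was 0.16 to 0.17 on the log2 scale, taken from repeated probes of like brightness as each has 1 spot. It does not allow for the disturbed tile of SIGLEC9. Copies inside disturbed tiles deviated by 0.90 (root mean square), against 0.22 outside.

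Among bright genes that were lower, ADI1 and LASP1 had the largest differences outside the disturbed tiles. ADI1, an enzyme of the methionine salvage pathway, read 9.85-fold lower with its brighter probe, but that spot sits at row 356 of column 85, next to the disturbed right edge, and the second ADI1 probe gave a log2 difference of -0.24. ADAMTS1, a secreted metalloprotease that cleaves proteoglycans, was lower in both of its probes, by 2.43-fold and 3.04-fold, and both lay outside the disturbed tiles. VSTM1, an immunoglobulin-like receptor, was 2.59-fold lower. The other 8 of the 12 most strongly lower bright genes lay in disturbed tiles, so their values carry the error of that area. They were CD101 (4.93-fold), ACP4 (3.88-fold), the collagen receptor subunit ITGA2 (3.42-fold), the endocytic scaffold ITSN2 (3.06-fold, its second probe giving a log2 difference of -0.47), the SUMO ligase PIAS1 (2.98-fold), the proteasome activator subunit PSME3 (2.76-fold), LAGE3 (2.42-fold) and the collagen prolyl isomerase FKBP10 (2.28-fold). After the local median of the differences was subtracted, CD101, ITGA2 and ACP4 had log2 differences of -1.90, -1.70 and -1.55. PSME3, PIAS1 and ITSN2 had -1.45, -1.33 and -1.24, while LAGE3 and FKBP10 came to -0.81 and -0.76. A local median cannot remove scatter from spot to spot, so these values do not show that the genes were lower.

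**Figure D3:**
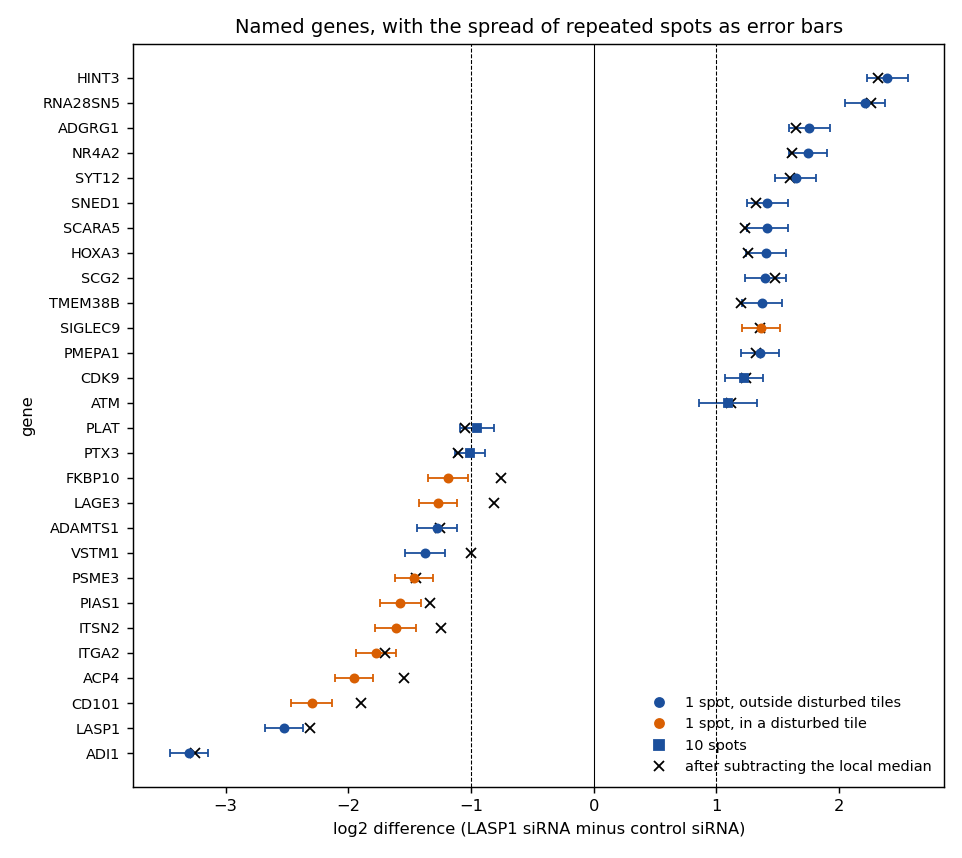
Log2 difference (LASP1 siRNA minus control siRNA) of the 12 most strongly higher and 12 most strongly lower bright genes and of 4 repeated-spot genes. Error bars are the technical SD of spots of one probe (own copies for genes with 10 spots, otherwise the median over repeated probes of like brightness), orange marks spots in disturbed tiles and crosses the value after subtracting the local median. Of the lower genes 8 are orange, and 1 of the higher genes. For orange genes the bars do not allow for the scatter of disturbed tiles, where copies deviated by 0.90 (root mean square) against 0.22 outside.

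Genes printed 10 times gave the best-measured values, and 4 of them, chosen after their values were seen, stood out. CDK9, the kinase that releases paused RNA polymerase II, was 2.34-fold higher (log2 difference 1.22, technical SD 0.16 over its own copies). ATM, the kinase that signals DNA double-strand breaks, was 2.14-fold higher (technical SD 0.24), although its single-copy probe, which lies in a disturbed tile, gave -0.01. PTX3, a secreted pattern recognition protein, was 2.01-fold lower (-1.01, SD 0.12), and just short of 2-fold with the median shift. PLAT, tissue-type plasminogen activator, was 1.94-fold lower (-0.95, SD 0.14).

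Some genes were well above background on 1 array only and have a bound in place of a fold, which holds for the main processing only. Each bound sets the brighter value against the dim array's own value or the lowest signal well above background on that array, whichever was higher. Where the dim array's own value was higher, the figure is a plain ratio to a value not well above background. Such figures are not floors and are given without "at least". Among the brightest seen only with control siRNA were FOXR2 (13.6-fold lower with LASP1 siRNA), OR8H3 (at least 10.99-fold), DTX4 (at least 8.80-fold) and CIMAP2 (8.56-fold). The brightest seen only with LASP1 siRNA were ITGA2B (18.3-fold higher), SLC22A10 (at least 20.9-fold), CPN2 (14.1-fold), KRTAP13-3 (at least 14.8-fold) and SFRP4 (at least 13.8-fold). Of the genes given here, all but KRTAP13-3 had their spot in a disturbed tile. In the authors' value table FOXR2, OR8H3, DTX4 and CIMAP2 again entered as bounds, with smaller log2 values of -3.14, -2.69, -2.38 and -2.35. A smaller bound there does not by itself show a smaller difference. With normexp these genes came to -0.88, -1.03, -0.89 and -0.70, all but OR8H3 short of 2-fold. ITGA2B, SLC22A10, CPN2, KRTAP13-3 and SFRP4 came to 1.61, 1.47, 1.28, 1.23 and 1.25 with normexp. The normexp offset shrinks the differences of such dim spots by itself, so these values do not show that the differences are smaller.

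Among 32 gene lists fixed before the data were examined, 6 had a median difference outside the middle 95% of 10000 random lists of the same size and brightness. Random draws of independent genes would place about 1.6 there. Members of a list can vary together, and some lists share members, so 1.6 does not measure chance between 2 arrays. Many members named here and below shrank by over 1.5 times on the log2 scale with normexp, some also after the local median was subtracted or with the signal before detrending. For dim members the normexp offset brings shrinkage by itself, so their normexp values here and below are no evidence against a difference. Replication-dependent histone genes were higher: 23 of 28 measured members, with a median log2 difference of 0.37 (percentile 100), and 0.37 without the disturbed tiles. H2AC20 was 1.79-fold higher. H2BC9 was 1.45-fold higher and H4C2 1.46-fold lower (log2 difference -0.17 with normexp), both in disturbed tiles. Genes of G2/M phase and mitosis were slightly lower, in 25 of 39 members, with a median of -0.08 (percentile 0.65), and -0.035 without the disturbed tiles. In this list ANLN was 1.61-fold lower (in a disturbed tile) and CDC20, the activator of the anaphase-promoting complex, 1.46-fold lower, while NUSAP1 was 1.57-fold and CENPA 1.43-fold higher. With normexp ANLN and CENPA came to log2 differences of -0.21 and 0.22. Both lists stood outside the random range under all 12 alternatives. Among these, the median shift and the filter for both arrays cannot change a list's percentile. A list outside in the main setting stays outside under them, here and below. Hypoxia and glycolysis genes were lower in 20 of 30 members, with a median of -0.13 (percentile 0.28), outside under 10 of 12 alternatives. The median was -0.053 without the disturbed tiles, and -0.036 (inside the range) after the local median was subtracted; normexp also put the list inside. ALDOC, an aldolase, was 1.98-fold lower in a disturbed tile, the enolase ENO2 1.47-fold lower and the histone demethylase KDM3A 1.42-fold lower, with ALDOC and KDM3A at -0.36 and -0.30 on the log2 scale with normexp.

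The other 3 lists outside the range depended on the processing. Type I interferon-stimulated genes had a median of -0.10 (percentile 2.02, outside under 6 of 12 alternatives), with 23 of 37 members lower, and -0.043 without the disturbed tiles. Among them PARP9 was 1.70-fold lower in a disturbed tile, the RNA sensor IFIH1 1.40-fold lower and IFIT5 1.42-fold higher, with PARP9 at -0.32 on the log2 scale with normexp. NF-kB targets and inflammatory cytokines had a median of -0.10 (percentile 1.94, outside under 6 of 12 alternatives), which was 0.0067 without the disturbed tiles. BIRC3, an inhibitor of apoptosis, was 1.77-fold lower, IL6 1.58-fold lower (technical SD 0.83 over its own copies, and a log2 difference of -0.26 without those in disturbed tiles) and the prostaglandin synthase PTGS2 1.53-fold higher (SD 0.07; log2 difference 0.38 with normexp). Actin cytoskeleton and stress fibre genes, the structures LASP1 binds, had a median of -0.08 (percentile 1.65, outside under 3 of 12 alternatives), which turned to 0.068 after the local median was subtracted, 0.027 with the signal before detrending and 0.011 with normexp. TMSB4X, the actin monomer-binding thymosin beta-4, was 1.69-fold higher by its brighter probe (log2 difference 0.47 with normexp) and 2.78-fold by the other. CNN2, a calponin, was 1.60-fold higher in a disturbed tile, and the crosslinker ACTN1 was 1.45-fold lower.

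**Figure D4:**
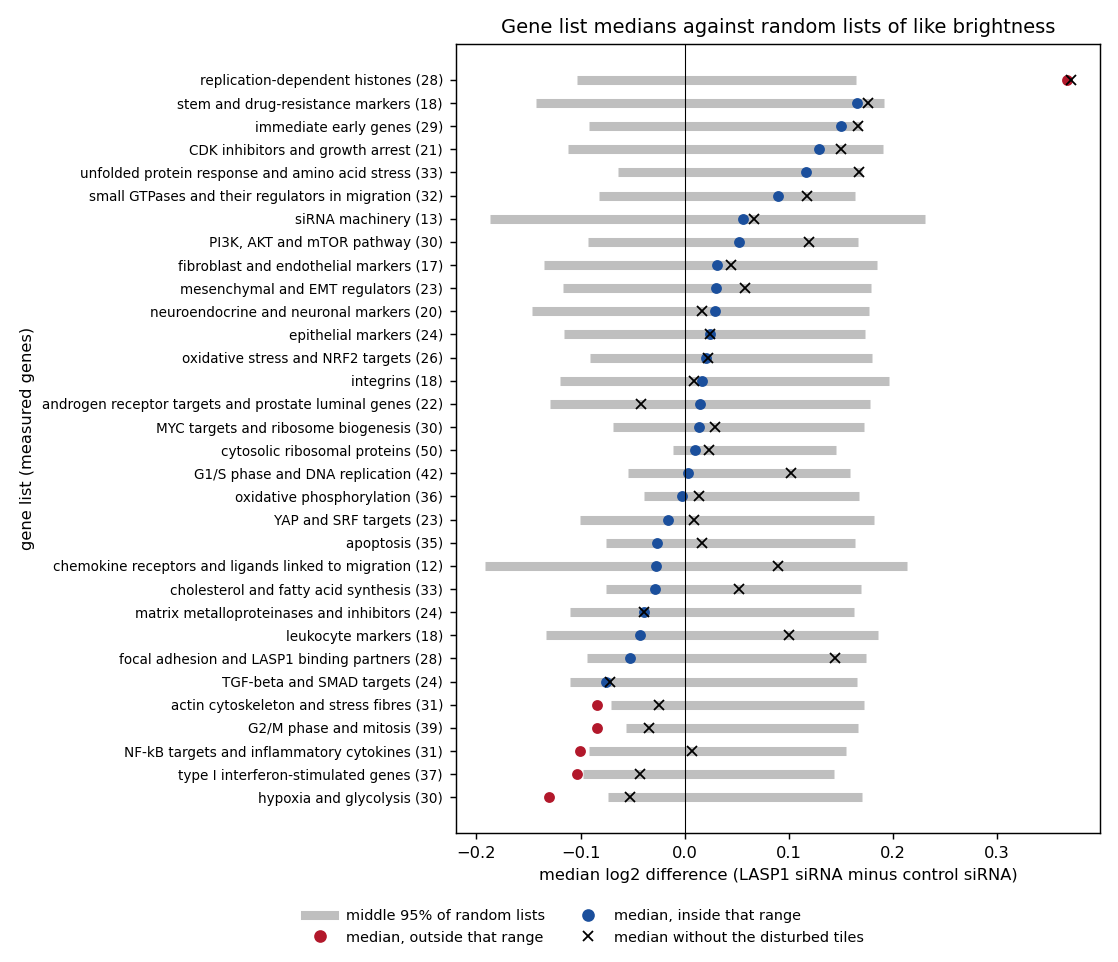
Median log2 difference (LASP1 siRNA minus control siRNA) of each gene list, with the number of measured genes in parentheses, against the middle 95% of 10000 random lists of like brightness (grey bars). Red points lie outside and blue points inside that range, and crosses give the median without the disturbed tiles. Replication-dependent histones (0.37) stand far above their bar, and 5 lists lie just below theirs.

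The lists nearest to cell adhesion and movement lay inside the random range. Here and in the lists below medians were small, and several turned under an alternative. Focal adhesion genes and LASP1 binding partners had a median of -0.05 (percentile 8.44), with 13 members higher and 15 lower, and the median was 0.14 without the disturbed tiles. In this list LIMK1, the kinase that inactivates cofilin, was 1.82-fold higher and ENAH 1.74-fold higher, although a second ENAH probe gave -0.30. PARVA was 1.83-fold lower in a disturbed tile, and LPP, a dim gene, was 2.52-fold higher, but 0.40 on the log2 scale with normexp. Integrins had a median of 0.02 (percentile 36.3, outside under 1 of 12 alternatives). ITGA10 was 2.10-fold and ITGB8 2.09-fold higher, while ITGA2 was lower, as given above. ITGA9, dim and in a disturbed tile, was 2.93-fold lower. With normexp ITGA10, ITGB8 and ITGA9 came to log2 differences of 0.84, 0.65 and -0.54, short of 2-fold. Small GTPases and their regulators had a median of 0.09 (percentile 78.2), with 20 members higher and 12 lower. There RND1 and CDC42EP3, both dim and the latter in a disturbed tile, were higher by log2 differences of 1.32 and 0.90, but by 0.25 and 0.26 with normexp. RHOB and PAK1, both in disturbed tiles, were 1.52-fold and 1.46-fold lower, although a second RHOB probe gave 0.13. Matrix metalloproteinases and inhibitors had a median of -0.04 (percentile 15.3), with the urokinase receptor PLAUR 1.55-fold lower, MMP1 1.47-fold lower (SD 0.22 over its own copies) and MMP14 1.53-fold higher. Migration-linked chemokine genes had a median of -0.03 (percentile 30.8), and CXCL16 was 1.42-fold lower.

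Mesenchymal and EMT regulators had a median of 0.03 (percentile 47.6), with 12 members higher and 11 lower. Within the list COL1A1, a type I collagen chain, was 3.06-fold higher, SPARC 2.55-fold (in a disturbed tile), SNAI1 1.54-fold and CDH2 1.51-fold, although the second CDH2 probe gave -0.08. Epithelial markers had a median of 0.02 (percentile 45.0), with the tight junction protein CLDN1 1.61-fold lower and MUC1 1.54-fold higher by the brighter of 2 probes, the other giving -0.06. Stem and drug-resistance markers were higher in 15 of 18 members (median 0.16, percentile 95.2, outside under 2 of 12 alternatives), and SOX9, a transcription factor, was 2.15-fold higher (log2 difference 0.91 with normexp). Immediate early genes were higher in 22 of 29 members (median 0.15, percentile 95.5, outside under 1 of 12). In this list NR4A2 was higher, as given above, while MCL1, an inhibitor of apoptosis, was 1.48-fold lower. Androgen receptor targets and prostate luminal genes had a median of 0.01 (percentile 43.7), with TMPRSS2 2.93-fold higher at low signal in a disturbed tile, and short of 2-fold with normexp. Neuroendocrine and neuronal markers had a median of 0.03 (percentile 54.5), and SCG2 was higher, as given above.

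Growth and signalling lists were also inside the range. G1/S phase and DNA replication genes split evenly, 21 higher and 21 lower (median 0.00, percentile 18.7), with the uracil glycosylase UNG 1.71-fold, UHRF1 1.56-fold and RRM2 1.45-fold higher. CDK inhibitors and growth arrest genes were higher in 15 of 21 members (median 0.13, percentile 87.0). There TXNIP, which binds thioredoxin, was 2.12-fold (log2 difference 0.76 with normexp) and RB1 1.60-fold higher (SD 0.16 over its own copies), while GADD45A and CDKN1C, both in disturbed tiles, were 1.93-fold and 1.77-fold lower. Apoptosis genes had a median of -0.03 (percentile 11.4), with CASP10 1.60-fold higher by the brightest of 4 probes and CASP1 1.83-fold lower. TGF-beta and SMAD targets had a median of -0.08 (percentile 6.44). PMEPA1 was higher, as given above, while CCN1 was 1.55-fold lower and CCN2 1.80-fold lower in a disturbed tile. YAP and SRF targets, which share those CCN genes, had a median of -0.02 (percentile 20.6), with the focal adhesion protein VCL 1.41-fold lower. PI3K, AKT and mTOR pathway genes had a median of 0.05 (percentile 60.9), with PIK3CB 1.47-fold lower and FOXO1, dim and in a disturbed tile, 3.29-fold lower, but -0.40 on the log2 scale with normexp.

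Among metabolic and housekeeping lists, cholesterol and fatty acid synthesis genes had a median of -0.03 (percentile 10.0), with SREBF1 1.58-fold higher by its brighter probe, the other giving 0.16. Unfolded protein response and amino acid stress genes had a median of 0.12 (percentile 84.1), with PDIA4 1.55-fold higher and VLDLR 1.58-fold lower. Oxidative stress and NRF2 targets had a median of 0.02 (percentile 33.4), with ferritin light chain FTL 1.66-fold and NQO1 1.59-fold higher. Oxidative phosphorylation genes had a median of 0.00 (percentile 9.76), cytosolic ribosomal proteins 0.01 (percentile 7.30) and MYC targets and ribosome biogenesis genes 0.01 (percentile 25.7), and each of these 3 lists was outside under 3 of 12 alternatives. Examples were ATP5F1C, 1.49-fold lower, RPS3, 1.43-fold lower, and NOLC1, 1.71-fold higher. The siRNA machinery had a median of 0.06 (percentile 63.0), with TNRC6C 1.53-fold and DICER1 1.42-fold higher. Of the markers of other cell types, leukocyte markers had a median of -0.04 (percentile 18.3), and fibroblast and endothelial markers 0.03 (percentile 49.7). CD3D and CD14, 8.65-fold and 2.19-fold lower, both lay in disturbed tiles and came to log2 differences of -0.88 and -0.41 with normexp, while PDGFRA was 1.91-fold higher.

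Most genes rest on a single spot on each array. Of 64 genes past 2-fold that had several probes measured on both arrays, 26 had a probe of opposite sign.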

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

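No paired analysis was possible because each group has 1 array. The alternatives with the disturbed tiles left out, the local median subtracted and the signal before detrending were chosen after seeing the data. LASP1 stayed lower under all 11 alternatives, from -2.56 to -2.30. With 1 probe outside the disturbed tiles, the alternatives for tiles, dim genes and probe means could not change its value. LASP1 moved by more than the technical SD with normexp (-2.30), the local median subtracted (-2.31) and the signal before detrending (-2.34). The 288 genes at least 2-fold higher became 88 with normexp, which also added an offset and used median spot signals, and 183 without the disturbed tiles. That offset can by itself take dim genes below 2-fold, in both directions. The 398 lower genes became 35 with normexp, 210 when both arrays had to be above background, 731 with no filter on dim genes and 82 without the disturbed tiles, and all 82 were among the 398. Other alternatives kept both counts within 1.5 times. Between 4 and 7 lists lay outside the random range. The actin median changed sign with normexp (0.011), the local median subtracted (0.068) and the signal before detrending (0.027). Against random lists it then lay at percentiles 50.4, 63.8 and 54.6. The NF-kB median changed sign without the disturbed tiles (0.0067, percentile 21.3). In each case the low position was lost, and the list did not become high among random lists. Apart from the tiles' own effect on the NF-kB list, the cause was not tested. None of the 52 named genes past 2-fold changed sign under any alternative that could measure it, but this was partly built in. By rule, the most strongly changed bright genes had the same direction in all probes, after quantile normalization and in the authors' value table. The median shift and the filters on dim genes could not turn a 2-fold difference. Genes with spots only in disturbed tiles had no value without those tiles. Signal over background limits the dim genes. In the dimmest 20% of probes the technical SD is 0.52 over all spots, part of it from the disturbed area, and 0.30 over spots outside the disturbed tiles.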

Other observations

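The tests of explanations in this part, and the values without the disturbed tiles and before detrending, were chosen after the result was seen, while the replication-dependent histone and G1/S lists were fixed before. RNAs that normally lack a poly(A) tail were measured beside the coding genes, and the genes and lists of this paragraph, apart from the replication-dependent histones and RNA28SN5, were chosen after their kind was seen to differ. The small-subunit rRNA RNA18SN5 was 9.20-fold higher with LASP1 siRNA, from a spot in a disturbed tile, while the 4 probes of RNA28SN5 lay outside the disturbed tiles. Other structured non-coding RNAs (small nucleolar, Cajal body and related RNAs) were higher in 21 of 31 genes, with a median log2 difference of 0.14 (percentile 97.2), outside the random range under 7 of 12 alternatives. Without the disturbed tiles the median was 0.18 (percentile 98.1). Histone genes expressed outside S phase, such as H2AZ1 and H3-3A, had a median of 0.00 over 9 genes (percentile 30.5), against 0.37 for the replication-dependent histones.

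Lower genes clustered in one area of the array: the share of single-copy probes at least 2-fold lower was 30.5 times higher inside the disturbed tiles than outside. RHOH shows it within 1 probe: its copy inside was 5.17-fold lower, and the 9 copies outside averaged 0.03 (SD 0.10). For 131 repeated probes with a copy at least 2-fold lower inside, the copies outside had a median difference of 0.014. Those low copies therefore do not reflect lower expression of their genes. The tiles were chosen because such copies disagree, so this was partly built in, and it does not cover probes printed once. The signal before detrending argues against the detrending of the control siRNA array alone as the cause. With it, the tiles still held 5.43 times their share of the lower probes. Detrending did bear on the size of the pattern. Before it, 5.90% of single-copy probes inside the tiles were at least 2-fold lower, against 9.18% in the main setting. The median difference inside was 0.0005 before detrending and -0.23 in the main setting. Uneven hybridisation or washing stays an open candidate explanation.

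The second pattern is that rRNA and replication-dependent histone probes were higher with LASP1 siRNA. The disturbed area does not account for it, since the histone median was 0.37 without those tiles. One candidate explanation is more RNA without a poly(A) tail in the labelled LASP1 siRNA sample, for example from RNA integrity or priming. The other structured non-coding RNAs leave this open, as their median of 0.14 (0.18 without those tiles) lies short of the 0.37 of the histones and members went both ways. A larger share of cells in S phase stays open for the histones too. The G1/S list had a median of 0.0035 (percentile 18.7), and 0.10 without the disturbed tiles (percentile 61.6). It lay inside the random range under all 12 alternatives, so no rise of that list was seen, but a small one is not excluded. With 1 array per group these explanations, and an untested direct effect of LASP1 siRNA, cannot be told apart.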
